A study of Mus musculus with 12 samples.

How the data were processed

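Bulk RNA-seq of mouse liver was analysed from 12 libraries, 1 per animal. The animals are told apart by their ear tags in the labels, so replicates are separate mice. Per the labels, total RNA was extracted with Trizol and cleaned on columns, and libraries were made with the KAPA mRNA HyperPrep kit. Per the labels' protocols, they were sequenced as paired reads of 76 bases on an Illumina HiSeq instrument, read quality was examined with FASTQC, and adaptors and poor reads were removed with Trimmomatic 0.35. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.2 and HTSeq were used with the mouse genome build GRCm38. The release of the gene annotation, the use of strand, the treatment of reads that map to several places and any filter on genes are not given in the sources used here. The values the authors deposited are whole-number counts of reads per gene, not normalised, in 1 table of 24983 genes by 12 libraries.

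Groups were taken from the labels: chow, and NASH diet with a minipump releasing polyethylene glycol (vehicle), oleic acid (OA) or nitro-oleic acid (OA-NO2). Replicate numbers follow the order of deposit and pair no animals. A symbol was found for 24914 of the gene identifiers. The 69 without one held 0.0143% of counts, and 8 symbols were shared by several identifiers. No entry stood for anything other than a gene, and 0 columns were left unmapped. Coordinates are those of GRCm38 from the GENCODE M21 annotation, 1-based. Total counts ran from 8462590 (chow replicate 1) to 20613777 (vehicle replicate 3), and the second lowest total was 15972613. In pairwise chi-square comparisons of replicates, the lowest chi-square per degree of freedom was 24.3, and 0 libraries differed from another by less than sampling noise.

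Genes with enough counts were kept with the default filter of edgeR (minimum count 10, minimum total 15), which left 14469. Libraries were scaled by trimmed mean of M values (TMM). All 12 libraries entered 1 quasi-likelihood model in edgeR 4.0.16 (R 4.3.3), with 1 coefficient per group, and contrasts were tested with Benjamini-Hochberg adjustment over the 14469 genes. A gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.226. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic, which is approximate, and 95% intervals use the same error. CPM, the usual normalised counts, were computed on the TMM-scaled totals. CPM of mitochondrial transcripts used the plain totals. A fold change is not printed for a gene with 4 or fewer counts over the 3 libraries of a group.

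Before the data were examined, 34 gene lists (566 genes, 3 of them missing from the table) were fixed for liver metabolism, injury, and cell types that liver tissue can hold. Of these, 32 had at least 5 tested genes and were tested with camera in limma 3.58.1 at its preset correlation of 0.01, against all other genes, with adjustment over the 32. The same test with a correlation estimated from the residuals, and the rotation test fry, were run beside it. The mixed form of fry asks for changes in either direction and gives none for the list. The lists cover matrix and fibrosis, stellate cells, Kupffer cells, monocyte-derived macrophages, lymphocytes, neutrophils, cholangiocytes, endothelium, red blood cells, adipose and pancreatic carryover, hepatocyte identity, chemokines and cytokines, antigen presentation, interferon response, acute phase, antioxidant (NRF2) genes, heat shock, unfolded protein response, immediate early genes and proliferation. They also cover lipogenesis, lipid droplets and lipid uptake, fatty acid oxidation, cholesterol synthesis, sterol efflux (LXR), bile acids, drug metabolism, glucose metabolism, growth hormone and sex-biased genes, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, circadian genes, and nitric oxide and eicosanoid genes. A few genes sit in 2 lists, among them Mmp12, Spp1, Elovl3, Cidea, Cyp7b1 and Slco1a1. No gene of the Kupffer list sits in another list.

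Genes named in the text follow a rule fixed before the data were examined. For each of the first 4 comparisons it takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups' CPM values. Predicted and clone-named genes, pseudogenes, immunoglobulin and T-cell receptor segments, histones and the Mup family were passed over and only counted (219 of the 2786 genes called between vehicle and chow). Where fewer than 8 were called, all are named; where none was called in a direction, the 5 with the lowest p are given as values. The rule adds the 3 members with the lowest p of every list that passed its test or had at least 3 called members, and 14 genes given in every comparison (Col1a1, Timp1, Trem2, Gpnmb, Cd36, Cidec, Cyp7a1, Sqle, Scd1, Cyp4a14, Fgf21, Hmox1, Nqo1 and Hspa1b). It also adds called genes of the drug comparisons that opposed the diet. A few genes that the rule selects are withheld and not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Genes with near-identical copies (the Mup, Serpina1, Cyp4a, Gsta, Gstm, Orm, Saa, Hba and Hbb families) and overlapping or antisense genes are uncertain, because counting could split or share their reads.

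The share of diet-called genes whose sign was opposed in another comparison was computed with a jackknife error over libraries, and beside it the mean of 40 simulations in which the later comparison held no effect, which also gave the slopes on the diet response expected without one. The simulations drew each gene independently, so they leave out differences between livers that move many genes together. Each library was placed on the diet response by projecting its log2 CPM over the 2786 diet-called genes onto the line from the chow mean (0%) to the vehicle mean (100%), and the OA and OA-NO2 positions were compared with a two-sided exact permutation test, which with 3 against 3 cannot give a p under 0.1. A gene's distance from its group's mean position was tested as a contrast in the same edgeR model, with that position taken as exact. For the mitochondrial transcripts, every 76-base window of each was searched for exact matches in the annotated pseudogenes of a copy on chromosome 1. At the place of mt-Atp8 no pseudogene is annotated, so it counted as not searched and was left out of the comparison of the other 12, a choice made after its values were seen.

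The tests were run on simulated counts drawn from the real means and library sizes with 200 of the 14469 genes changed. Between vehicle and chow, 48% of 2-fold, 88% of 4-fold and 100% of 8-fold changes were recovered, with 3.1% false calls. The shares were 40%, 76% and 94% between OA and vehicle (5.3% false), 50%, 84% and 94% between OA-NO2 and vehicle (4.2% false), and 50%, 82% and 84% between OA-NO2 and OA (0.9% false). Of 1.5-fold changes only 10%, 6%, 2% and 4% were recovered in these comparisons, in the same order. Genes were drawn independently around their mean over all 12 libraries. Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, median-ratio (RLE) size factors, library size alone, other filters on low counts, a robust fit, only the 2 groups compared, an adjusted p under 0.10, and leaving out each library in turn. For single named genes, all alternatives means DESeq2, RLE factors and each library left out in turn. Chosen after seeing the data were thinning of all libraries to the lowest total, a term for 3 libraries rich in certain mitochondrial transcripts, and leaving out mitochondrial genes with their nuclear copies. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.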

Results

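Liver RNA was sequenced from 12 C57BL/6J mice in 4 groups of 3. One group ate standard chow. The other groups ate, for 24 weeks, a diet meant to bring on nonalcoholic steatohepatitis (NASH, fatty liver with inflammation), with 40% of calories from fat and with trans fat, fructose and cholesterol added. Each of these mice carried a minipump under the skin, a device that releases its contents at a steady rate. The pump held polyethylene glycol alone (vehicle), oleic acid (OA, a common monounsaturated fatty acid) or nitro-oleic acid (OA-NO2, oleic acid that carries a nitro group), both fatty acids at 5 mg/kg/day. The labels mention no pump in the chow-fed mice, so the diet and the pump could not be separated. The series was made to ask what nitro-fatty acids do to steatosis and fibrosis in fatty liver brought on by diet.

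Total counts were 8462590, 17482735 and 19082770 in chow replicates 1 to 3, and 18952322, 15972613 and 20613777 in the vehicle group. They were 16847880, 17334455 and 17379756 with OA, and 17449884, 19786604 and 17922575 with OA-NO2. Albumin (Alb) was the most abundant gene in every library, at 4.06% to 9.50% of counts. Mitochondrially encoded transcripts took 13.1% ± 2.13 of counts in chow, 9.37% ± 4.24 with vehicle, 8.36% ± 0.25 with OA and 8.01% ± 1.86 with OA-NO2 (SD, n = 3 each). The first principal component held 46.4% of the variance, with the chow libraries between -71.87 and -44.72 and the vehicle libraries between 22.46 and 54.36. OA replicate 3, at -13.48, stood apart from OA replicates 1 and 2, at 49.62 and 39.99. TMM scaling factors were 0.803 ± 0.039 in chow and 1.15 ± 0.022 with vehicle (SD, n = 3). With library size alone in place of TMM, the median log2 fold change of all genes was 0.51 for vehicle over chow, 0.42 for OA over chow and 0.34 for OA-NO2 over chow. It was -0.09 for OA over vehicle, -0.18 for OA-NO2 over vehicle and -0.11 for OA-NO2 over OA, so changes are given relative to the TMM scale.

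The diet response was measured by comparing vehicle-infused mice on the NASH diet with chow-fed mice. Many genes of scar matrix and of recruited macrophages rose, and many of sex-biased liver metabolism fell, as did the macrophage genes Cd163, Marco and Timd4. The 3 lists behind this passed camera, but with an estimated correlation between genes their adjusted p was 0.0958 to 0.171. Gpnmb, a glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), stood at 49.2 ± 18.7 CPM with vehicle against 0.35 ± 0.379 in chow (SD, n = 3 each), a log2 fold change of 7.56 ± 1.26 (SE, edgeR adjusted p = 0.00331). Col1a1, the main collagen of scar (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), stood at 52.6 ± 26.0 against 1.64 ± 0.586 CPM, a log2 rise of 5.05 ± 0.85 (adjusted p = 0.00338). Hsd3b5, a male-biased steroid dehydrogenase (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), stood at 0.204 ± 0.0150 against 56.6 ± 12.3 CPM, a log2 fold change of -8.07 ± 1.17 (adjusted p = 0.0025). In edgeR's quasi-likelihood test 2786 of 14469 genes were called, 1606 higher (57.6%) and 1180 lower, of which 1543 had a log2 fold change beyond 1 in size. The groups' CPM values did not overlap in 2751 of the called genes and in 39.4% of all genes, where chance gives 10%. Scaling by library size alone called 5758 genes, 5510 higher and 248 lower. Leaving out 1 library called 1200 without vehicle replicate 3, 1392 without chow replicate 1, 1457 without chow replicate 2 and 1521 without vehicle replicate 2.

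The other large rises were in Mmp12, the elastase of macrophages (log2 fold change 6.52 ± 0.99, adjusted p = 0.00254), and Sdcbp2, a syntenin (6.17 ± 1.11, adjusted p = 0.00411). Several genes were close to 0 in chow and are given as CPM. Timp1, an inhibitor of matrix proteases, stood at 6.05 ± 2.71 CPM with vehicle against 0.0520 in chow, and Elovl7, a fatty acid elongase, at 4.54 ± 2.00 against 0.0443. Sprr1a stood at 5.03 ± 2.75 CPM and Fabp3, a fatty acid binding protein, at 2.08 ± 0.965, each with 0 counts in chow. Gipc2 stood at 5.37 ± 3.96 CPM against 0.0213, and its adjusted p of 0.0117 became 0.0544 without chow replicate 2 (0.000312 to 0.0544 over all alternatives). The large falls included Cd163, the haemoglobin scavenger receptor of resident macrophages (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), by a log2 change of -4.71 ± 0.38 (adjusted p = 8.18e-05). They also included Marco, a macrophage scavenger receptor (-3.95 ± 0.80, adjusted p = 0.00667), Slco1a1, an organic anion transporter (-3.93 ± 0.60, adjusted p = 0.00254), and Serpina1e, 1 of a family of near-identical antitrypsins and so uncertain (-3.55 ± 0.79, adjusted p = 0.00986). Grm8 changed by -3.41 ± 0.88 (adjusted p = 0.0193), and its call was lost without chow replicate 1 or 2 or vehicle replicate 2 or 3 (adjusted p 0.0241 to 0.0744 on leaving out 1 library). Moxd1 stood at 0.0511 CPM against 15.2 ± 20.1 in chow and Adgrf1 at 0.0615 against 2.27 ± 1.43.

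Of the lists fixed in advance, 20 of 32 passed camera, 10 upward and 10 downward. In the matrix and fibrosis list 27 of 31 tested genes rose and 0 fell, 30 adjusted over the list alone, with a median log2 fold change of 2.34 (camera adjusted p = 2.17e-22, adjusted p = 0.171 with an estimated correlation). Vim, an intermediate filament of mesenchymal cells, rose by 1.82 ± 0.24 and Col6a1, a chain of collagen VI, by 1.99 ± 0.31. In the list of monocyte-derived macrophages 11 of 14 rose and 0 fell, 12 adjusted over the list alone (median 3.44, adjusted p = 1.06e-13; adjusted p = 0.171 with an estimated correlation). Trem2, a lipid receptor of macrophages, rose by 4.0 ± 0.61, and Cx3cr1, a chemokine receptor of monocytes, by 4.16 ± 0.61. In the antigen presentation list 9 of 9 rose, 9 adjusted over the list alone (median 2.60, adjusted p = 1.18e-15; adjusted p = 0.0958 with an estimated correlation), among them the class II genes H2-Aa (2.62 ± 0.35), H2-Ab1 (2.78 ± 0.35) and H2-Eb1 (2.60 ± 0.32). Among chemokines and cytokines 13 of 21 rose and 0 fell, 16 adjusted over the list alone (median 1.51, adjusted p = 1.77e-09; adjusted p = 0.0958 with an estimated correlation). Ccl5 rose by 2.96 ± 0.45, Cxcl16 by 1.57 ± 0.22, and Ccl22 at 1.54 ± 0.342 CPM against 0.0229.

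Markers of other cell types moved beside these groups. Of 10 cholangiocyte genes 7 rose, 9 adjusted over the list alone (median 2.37, adjusted p = 0.00021; adjusted p = 0.332 with an estimated correlation). Among them were Spp1, osteopontin (3.49 ± 0.78), Cftr, a chloride channel, at 1.25 ± 0.937 against 0.0427 CPM, and Cd24a (2.42 ± 0.60). Cftr lost its call without chow replicate 1 or 2 or vehicle replicate 2 or 3 (adjusted p 0.0111 to 0.0972), and Cd24a without chow replicate 1 or 2 or vehicle replicate 2 (0.00891 to 0.059). Of 12 stellate cell genes 5 rose, 5 adjusted over the list alone (median 0.70, adjusted p = 0.000166; adjusted p = 0.253 with an estimated correlation). Pdgfrb rose by 2.06 ± 0.46, Cygb by 1.65 ± 0.31 and Des by 1.5 ± 0.29. Of 18 proliferation genes 7 rose, 9 adjusted over the list alone (median 1.11, adjusted p = 8.49e-05; adjusted p = 0.171 with an estimated correlation). Mki67 rose by 1.80 ± 0.31, Top2a by 1.72 ± 0.34 and Mcm2 by 1.35 ± 0.27. Of 16 lymphocyte genes 2 rose, 0 adjusted over the list alone (median 1.2, adjusted p = 0.00682; adjusted p = 0.309 with an estimated correlation), the T-cell gene Cd8a (1.85 ± 0.61) and the granzyme Gzma (2.37 ± 0.75), and Nkg7 stood at 1.86 ± 0.62 (adjusted p = 0.0504). Cd8a lost its call without chow replicate 1 or 2 or vehicle replicate 1 or 3 (adjusted p 0.0326 to 0.15), and Gzma without any chow replicate or vehicle replicate 1 or 3 (0.04 to 0.155). Of 13 Kupffer cell genes 6 rose and 3 fell, 7 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.305), with a median of 0.75, a mean of -0.27 and camera pointing upward. Timd4, a receptor for dying cells, fell by 3.30 ± 0.56, while C1qb, a complement subunit, rose by 1.42 ± 0.24. Among list members chosen after their values were seen, C1qa rose by 1.2 ± 0.23, Cd5l by 1.13 ± 0.26 and Csf1r by 0.76 ± 0.23, the last lost without chow replicate 1 or 2 or any vehicle replicate (adjusted p 0.00788 to 0.13). In the same way Adgre1 stood at 0.75 ± 0.27 (adjusted p = 0.0721), Vsig4 at 0.22 ± 0.46 and Clec4f at -0.02 ± 0.21, which became 0.50 with library size alone.

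Of 17 growth hormone and sex-biased genes 13 fell and 1 rose, 14 and 1 adjusted over the list alone (median -1.69, adjusted p = 1.76e-09; adjusted p = 0.0958 with an estimated correlation). Summed over 42 Mup genes, the major urinary proteins, whose near-identical copies make single members uncertain, counts fell by 2.1 ± 0.26 on the log2 scale, and 18 of 31 tested members were called. Mup3 fell by 2.64 ± 0.39. Of 25 cholesterol synthesis genes 14 fell and 0 rose, 15 adjusted over the list alone (median -0.98, adjusted p = 5.57e-09; adjusted p = 0.252 with an estimated correlation). Stard4, a sterol carrier, fell by 1.60 ± 0.25, Tm7sf2, a sterol reductase, by 1.32 ± 0.20 and Hsd17b7 by 1.04 ± 0.15. Sqle, squalene epoxidase, changed by -1.53 ± 0.51 (adjusted p = 0.0495, 0.0239 to 0.397 on leaving out 1 library, and lost without chow replicate 1 or any vehicle replicate). Its log2 fold change ran from -1.9 to -0.4, the smallest without chow replicate 1. Of 17 bile acid genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone (median -0.53, adjusted p = 0.000191; adjusted p = 0.171 with an estimated correlation). Slc10a1, the main bile acid importer, fell by 1.83 ± 0.29 and Cyp7b1, an oxysterol hydroxylase, by 2.17 ± 0.38. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -0.69 ± 0.30 (adjusted p = 0.122, 0.0182 to 0.357 over all alternatives). Of 24 fatty acid oxidation genes 12 fell and 1 rose, 18 and 3 adjusted over the list alone (median -0.68, adjusted p = 1.62e-05; adjusted p = 0.27 with an estimated correlation). Cyp4a14 and Cyp4a10, fatty acid hydroxylases of a family with close copies, fell by 2.04 ± 0.49 and 1.86 ± 0.44. Hadha, an enzyme of mitochondrial oxidation, fell by 0.79 ± 0.18 (adjusted p = 0.0116, 0.0506 without vehicle replicate 2, 0.000132 to 0.0506 over all alternatives). The list's 1 rise was Fgf21, a hormone of fasting liver (1.81 ± 0.50), lost without chow replicate 2 or 3 or vehicle replicate 2 or 3 (adjusted p 0.0207 to 0.0979).

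Of 17 hepatocyte identity genes 9 fell and 0 rose, 11 adjusted over the list alone (median -0.76, adjusted p = 8.63e-06; adjusted p = 0.252 with an estimated correlation). Alb fell by 1.39 ± 0.29, Cps1, an enzyme of the urea cycle, by 1.62 ± 0.33, and the uncertain Serpina1a by 1.17 ± 0.27. Lipid droplet and lipid uptake genes moved both ways, 8 of 20 up and 2 down, 8 and 3 adjusted over the list alone (median 0.45, adjusted p = 5.01e-05; adjusted p = 0.0272 with an estimated correlation). Cidea, a lipid droplet protein also abundant in brown fat, rose by 4.16 ± 0.34 (adjusted p = 8.18e-05), Cidec, of the same family, by 1.77 ± 0.22 and Vldlr, a lipoprotein receptor, by 2.07 ± 0.29. Cd36, a fatty acid transporter, stood at 0.71 ± 0.35 (adjusted p = 0.175, 0.0173 to 0.432 over all alternatives). Of 22 antioxidant genes 12 rose and 0 fell, 13 adjusted over the list alone (median 0.72, adjusted p = 1.25e-08; adjusted p = 0.0272 with an estimated correlation). Gstm3 and Gsta1, glutathione transferases with close copies, rose by 4.34 ± 0.49 and 5.20 ± 0.70, and Srxn1, sulfiredoxin, by 1.30 ± 0.20. Nqo1 stood at 0.81 ± 0.24 (adjusted p = 0.0313, and 0.0521 to 0.108 on leaving out any 1 of the 3 chow and 3 vehicle libraries, so never called), and Hmox1, haem oxygenase, at 0.55 ± 0.28 (adjusted p = 0.184, 0.00644 to 0.47 over all alternatives).

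The remaining downward lists had higher camera adjusted p. Mitochondrially encoded genes had 2 of 13 lower, 5 adjusted over the list alone (median -0.97, adjusted p = 0.000596; adjusted p = 0.286 with an estimated correlation), with mt-Co1 at -1.21 ± 0.29 (adjusted p = 0.0681 without vehicle replicate 2, 6.96e-05 to 0.0681 over all alternatives) and mt-Nd2 at -0.94 ± 0.24. The latter lost its call without chow replicate 2 or any vehicle replicate (adjusted p 0.0336 to 0.0569). Of these 13 transcripts 6 were uneven within groups, and their summed share was 4.02% and 4.49% of counts in chow replicates 1 and 3 and 5.24% in vehicle replicate 3. Drug metabolism genes had 5 of 22 lower and 1 higher, 6 and 1 adjusted over the list alone (median -0.44, 0.08 with library size alone; adjusted p = 0.0187; adjusted p = 0.519 with an estimated correlation). Sult2a8, a bile acid sulfotransferase, fell by 2.32 ± 0.50, and Cyp3a11 rose by 1.61 ± 0.38 (adjusted p = 0.0564 without vehicle replicate 2, 0.000103 to 0.0564 over all alternatives). Circadian genes had 2 of 18 lower, 2 adjusted over the list alone (median -0.38, 0.13 with library size alone; adjusted p = 0.0261; adjusted p = 0.27 with an estimated correlation), Clock (-0.66 ± 0.15) and Nfil3 (-1.05 ± 0.27). Nfil3 lost its call without chow replicate 3 or vehicle replicate 2 or 3 (adjusted p 0.0189 to 0.0773). Nuclear genes of oxidative phosphorylation had 1 of 22 lower, 0 adjusted over the list alone (median -0.28, 0.25 with library size alone; adjusted p = 0.0172; adjusted p = 0.567 with an estimated correlation). That gene was Atp5c1 (-0.58 ± 0.19), not called without chow replicate 1 or 2 or any vehicle replicate (adjusted p 0.0396 to 0.151), and Ndufs1 and Sdhb stood at -0.61 ± 0.21 and -0.61 ± 0.22. Red blood cell genes had 1 of 6 lower, 1 adjusted over the list alone (median -0.88, adjusted p = 0.0354; adjusted p = 0.426 with an estimated correlation). It was Alas2, of haem synthesis (-1.13 ± 0.23), while the globins Hba-a1 and Hbb-bs, which have near-identical copies, stood at -0.97 ± 0.50 and -1.0 ± 0.52.

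**Figure D1:**
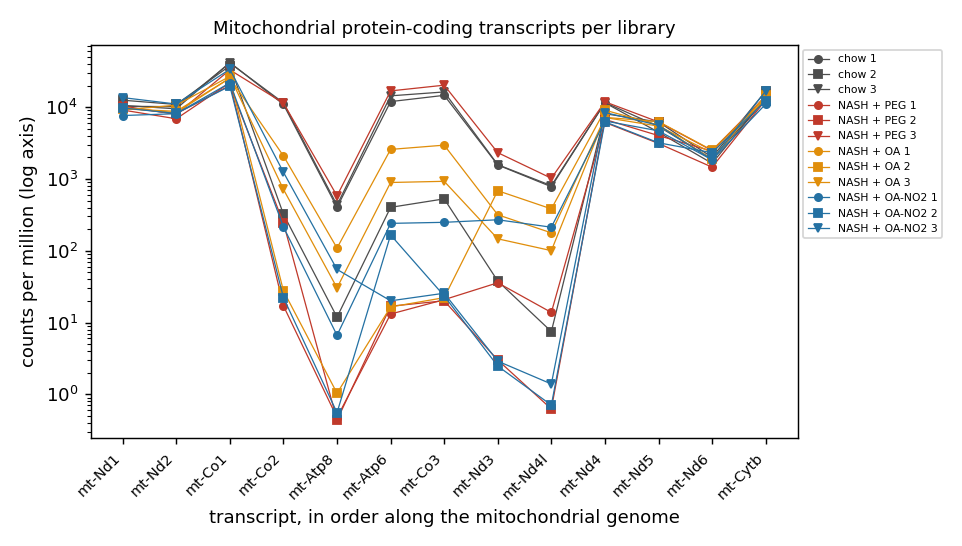
CPM (logarithmic vertical axis) of the 13 mitochondrial protein-coding transcripts are shown in their order along the mitochondrial genome (horizontal axis), with a line per library coloured by group. For 7 transcripts the within-group SD of log2 values lay between 0.178 and 0.351, and for mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l between 3.43 and 3.89.

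Lists that did not pass camera still held called genes. Among glucose genes 4 of 20 rose and 7 fell, 4 and 9 adjusted over the list alone (adjusted p = 0.18; median -0.46, 0.07 with library size alone). Hk2, a hexokinase low in healthy liver, rose by 2.66 ± 0.37, Pkm, a pyruvate kinase, by 1.75 ± 0.27, and Gys2, the liver glycogen synthase, fell by 1.54 ± 0.26. Among acute phase genes 6 of 17 rose and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.0693). Lcn2, lipocalin, rose by 3.12 ± 0.62, and Saa2 and Orm3, which have close copies, by 2.80 ± 0.55 and 1.90 ± 0.30. Among lipogenesis genes 2 of 21 rose and 4 fell, 3 and 4 adjusted over the list alone (adjusted p = 0.717; median -0.13, 0.38 with library size alone). Srebf1, the transcription factor of lipogenesis, rose by 1.44 ± 0.28 and Mogat1 by 1.27 ± 0.27, Acss2 fell by 0.90 ± 0.19, and Scd1, stearoyl-CoA desaturase, stood at 0.43 ± 0.21 (adjusted p = 0.169, 0.0437 to 0.436 over all alternatives). Heat shock genes had 3 of 13 lower and 1 higher, 7 and 1 adjusted over the list alone (adjusted p = 0.0624; median -0.45, 0.07 with library size alone). Hspb1 rose by 2.50 ± 0.43, the chaperones Hsph1 and Hspa8 fell by 1.07 ± 0.25 and 0.89 ± 0.21, the last with an adjusted p of 0.0553 without vehicle replicate 3 (0.000113 to 0.0553 over all alternatives), and Hspa1b stood at -0.83 ± 0.32. Of 18 interferon response genes 5 rose, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.0628), among them Oas1a (1.45 ± 0.28), Gbp2 (1.25 ± 0.24) and Oasl2 (1.01 ± 0.16). In the unfolded protein response list 3 of 20 rose and 1 fell, 4 and 2 adjusted over the list alone (adjusted p = 0.347). Sdf2l1 rose by 1.33 ± 0.41 and Trib3 by 1.35 ± 0.40, and Dnajc3 stood at -0.44 ± 0.13, which became 0.08 with library size alone. Sdf2l1 lost its call without any chow replicate or vehicle replicate 3 (adjusted p 0.0273 to 0.19; log2 fold change 0.79 without vehicle replicate 3), Trib3 without chow replicate 1 or 2 or vehicle replicate 2 or 3 (0.00671 to 0.124; log2 fold change 2.12 without chow replicate 3), and Dnajc3 without chow replicate 1 or 2 or any vehicle replicate (0.0398 to 0.0981). No other list passed, and their medians were 0.23 for immediate early genes (1 of 14 rose, 0 adjusted over the list alone), 0.13 for sterol efflux (2 of 11 rose, 3 and 1 lower adjusted over the list alone), 0.12 for nitric oxide and eicosanoid genes (1 of 7 rose and 1 fell, the same counts adjusted over the list alone), and 0.03 for endothelium (0 of 12, 0 adjusted over the list alone). These counts are those of edgeR, and DESeq2 called 1 endothelial gene higher. For neutrophils the median was 0.56 (0 of 5 by edgeR and 0 by DESeq2, 0 adjusted over the list alone). Of 4 tested adipose carryover genes 2 rose, 2 adjusted over the list alone (median 1.10), Cidea and the complement factor Cfd, and the 1 tested pancreatic gene stood at 0.03.

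**Figure D2:**
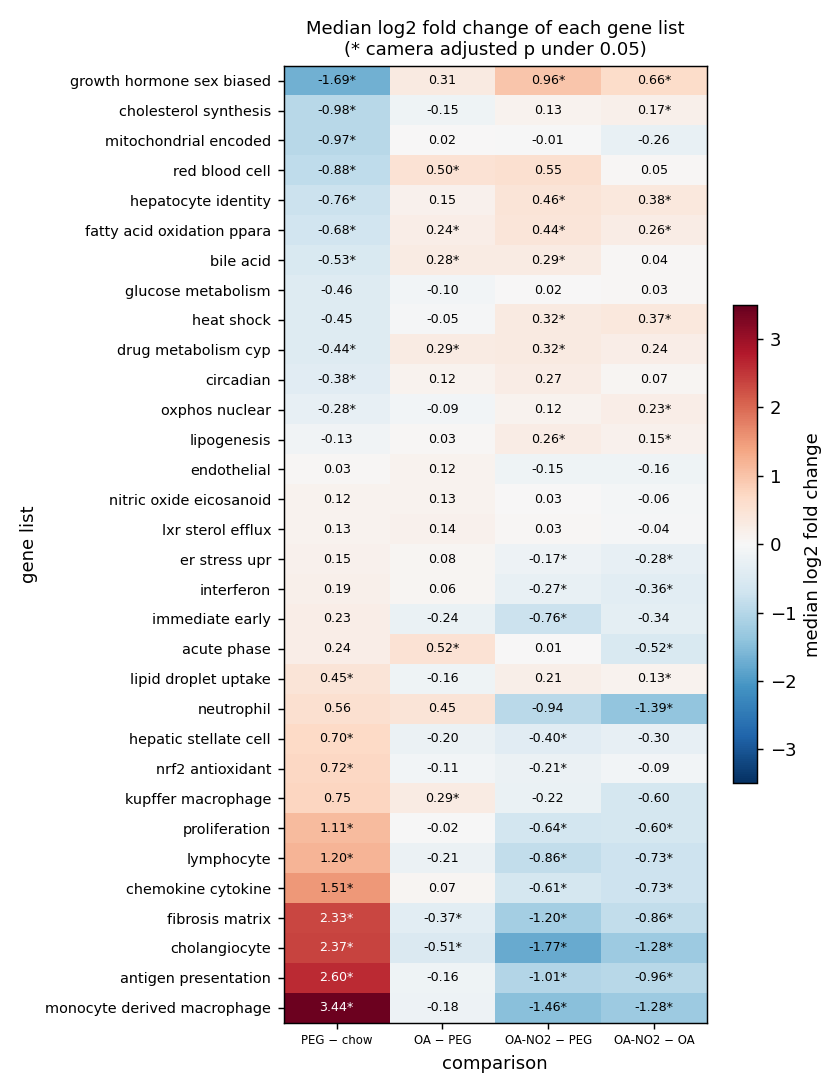
Each cell gives the median log2 fold change of a gene list (vertical axis, 32 lists) in a comparison (horizontal axis; PEG is the vehicle), by colour and number, with an asterisk where the camera adjusted p was under 0.05. The fibrosis matrix list stood at 2.34 for vehicle over chow and at -1.2 for OA-NO2 over vehicle, while with library size alone the vehicle-over-chow medians of the oxidative phosphorylation, drug metabolism, circadian, lipogenesis, heat shock and glucose lists turned from negative to positive.

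The effect of unmodified oleic acid was measured against vehicle, both on the NASH diet. No single gene was called, so the genes with the lowest p are given as values. Cxcl1, a neutrophil chemokine, stood at 16.1 ± 3.16 CPM with OA against 7.10 ± 2.00 with vehicle (SD, n = 3 each; log2 fold change 1.19 ± 0.28 SE, edgeR adjusted p = 0.975). Kcnj16, a potassium channel, stood at 1.40 ± 0.33, Il1r1, the interleukin-1 receptor, at 1.03 ± 0.27, Steap4, a metalloreductase of the acute phase list, at 0.87 ± 0.23 and Hook3 at 0.48 ± 0.13. On the lower side were Igfbp5 (-2.03 ± 0.58), Cavin1 (-0.85 ± 0.20), Depp1 (-0.73 ± 0.22), Nudt18 (-0.63 ± 0.19) and Map1lc3a (-0.47 ± 0.14), all at an adjusted p of 0.975. For Col1a1 the difference was -0.60 with a 95% interval of -1.98 to 0.78, for Trem2 -0.24 (-1.24 to 0.77), for Gpnmb 0.19 (-1.40 to 1.78) and for Scd1 0.28 (-0.18 to 0.74). Among the genes given in every comparison the values ran from -0.88 ± 0.63 for Timp1 and -0.86 ± 0.46 for Fgf21 to 0.38 ± 0.35 for Cd36 and 0.39 ± 0.47 for Cyp4a14. edgeR called 0 genes with 564 at an unadjusted p under 0.05, where chance gives 723. DESeq2 called 0 (532 unadjusted) and limma-voom 0 (586 unadjusted). CPM values did not overlap in 13.1% of genes, where chance gives 10%.

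With OA, 8 lists passed camera, 6 upward and 2 downward, and 0 passed with an estimated correlation or with either form of fry. Of 17 acute phase genes 17 had positive values (median 0.52, camera adjusted p = 2.48e-08; adjusted p = 0.717 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. They included Orm3, with close copies, at 0.72 ± 0.27 and Itih3 at 0.57 ± 0.23. Of 31 matrix genes 30 had negative values (median -0.37, adjusted p = 1.55e-05; adjusted p = 0.732 with an estimated correlation). Col6a1 stood at -0.62 ± 0.29 and Sparc at -0.57 ± 0.30, while Fn1, fibronectin, stood at 0.42 ± 0.19. The other 6 lists were at adjusted p = 0.732 with an estimated correlation and held 0 called genes, 0 adjusted over the list alone. Their medians were 0.24 for fatty acid oxidation (adjusted p = 0.012; Ppara 0.40 ± 0.24), 0.29 for Kupffer cells (adjusted p = 0.012; Clec4f 0.39 ± 0.21, Adgre1 0.50 ± 0.27) and 0.50 for red blood cells (adjusted p = 0.012; Alas2 0.51 ± 0.23). They were -0.51 for cholangiocytes (adjusted p = 0.013; Krt19 -0.92 ± 0.60, Krt7 -0.95 ± 0.57), 0.29 for drug metabolism (adjusted p = 0.013; Nr1i3 0.64 ± 0.39) and 0.28 for bile acids (adjusted p = 0.0367; Slc10a1 0.41 ± 0.28). Without vehicle replicate 3, 4 lists passed. Median and mean differed in sign in 3 lists that did not pass. They were the mitochondrial list (0.02 and -0.67, camera upward), the unfolded protein response (0.08 and -0.05, camera upward) and nitric oxide and eicosanoid genes (0.13 and -0.01, camera downward). Cd163 stood at 1.35 ± 0.709 CPM with OA against 0.638 ± 0.341 with vehicle, a difference of 1.10 (95% interval 0.19 to 2.00, adjusted p = 0.975).

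The effect of nitro-oleic acid was measured against vehicle, both on the NASH diet. Cd163 stood at 18.4 ± 3.81 CPM with OA-NO2 against 0.638 ± 0.341 with vehicle (SD, n = 3 each), a log2 rise of 4.86 ± 0.38 (SE; 95% interval 4.03 to 5.68, edgeR adjusted p = 9.81e-05, 2.04e-34 to 0.00256 over all alternatives), beside 16.7 ± 1.90 CPM in chow. Nlrp12, a receptor that restrains inflammatory signalling (ENSMUSG00000078817, chromosome 7, 3218784 to 3249740), rose by 1.70 ± 0.24 (adjusted p = 0.0377), from 34.6 ± 7.83 to 112 ± 16.7 CPM. On leaving out 1 library its adjusted p ran from 0.0306 to 0.188, and the call held only without OA-NO2 replicate 1, being lost without OA-NO2 replicate 2 or 3 or any vehicle replicate. Mup17, named after its values were seen and uncertain for its near-identical copies, rose by 3.49 ± 0.51 (adjusted p = 0.0436, 0.0538 to 0.262 on leaving out any 1 of the 3 vehicle and 3 OA-NO2 libraries, so never called). Summed over 42 Mup genes the log2 difference was 1.02 ± 0.25, and 0.91 to 1.18 without 1 OA-NO2 library. These 3 were the only genes called by edgeR, with 2281 at an unadjusted p under 0.05 (1049 higher, 1232 lower) where chance gives 723. CPM values did not overlap in 19.7% of genes, where chance gives 10%. DESeq2 called 300 genes (131 higher, 169 lower), edgeR without a filter on low counts 151, edgeR on the 2 groups alone 62, and edgeR with a mean of at least 1 CPM required 1. Leaving out vehicle replicate 1, 2 or 3 or OA-NO2 replicate 3 left 1 gene called.

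Genes of resident macrophages differed from one another. Marco stood at 28.7 ± 24.0 CPM with OA-NO2 against 1.29 ± 0.713 (log2 4.50 ± 0.81, edgeR adjusted p = 0.0965, DESeq2 adjusted p = 0.00103, 0.00103 to 0.448 over all alternatives). Timd4 stood at 7.25 ± 4.2 against 0.861 ± 0.0213 CPM (3.07 ± 0.55, edgeR adjusted p = 0.0965, DESeq2 adjusted p = 8.82e-06, 8.82e-06 to 0.448 over all alternatives). Both were chosen in this comparison after their values were seen, as were C1qa (-0.61 ± 0.23), Cd5l (-0.43 ± 0.26), Adgre1 (-0.31 ± 0.27), Csf1r (-0.16 ± 0.23), Clec4f (0.28 ± 0.21) and Vsig4 (0.07 ± 0.46, -0.15 with library size alone). In the Kupffer list 1 of 13 genes rose, and 3 rose and 2 fell adjusted over the list alone. The list did not pass (adjusted p = 0.0781), with a median of -0.22, a mean of 0.72 and camera pointing upward. The lowest p values on the lower side, none called by edgeR and all called by DESeq2, were in Cd34, a marker of capillary endothelium and progenitors (-2.18 ± 0.36, adjusted p = 0.0948), Ntrk2 (-1.01 ± 0.19, adjusted p = 0.113), Ccdc85b (-0.80 ± 0.15, adjusted p = 0.124), Cxcl16 (-1.05 ± 0.21, adjusted p = 0.138) and Dync2li1 (-1.77 ± 0.35, adjusted p = 0.138). Their DESeq2 adjusted p were 9.62e-05, 0.00125, 0.00186, 0.00276 and 0.00753, each the lowest over all alternatives, where the highest was 0.448.

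**Figure D3:**
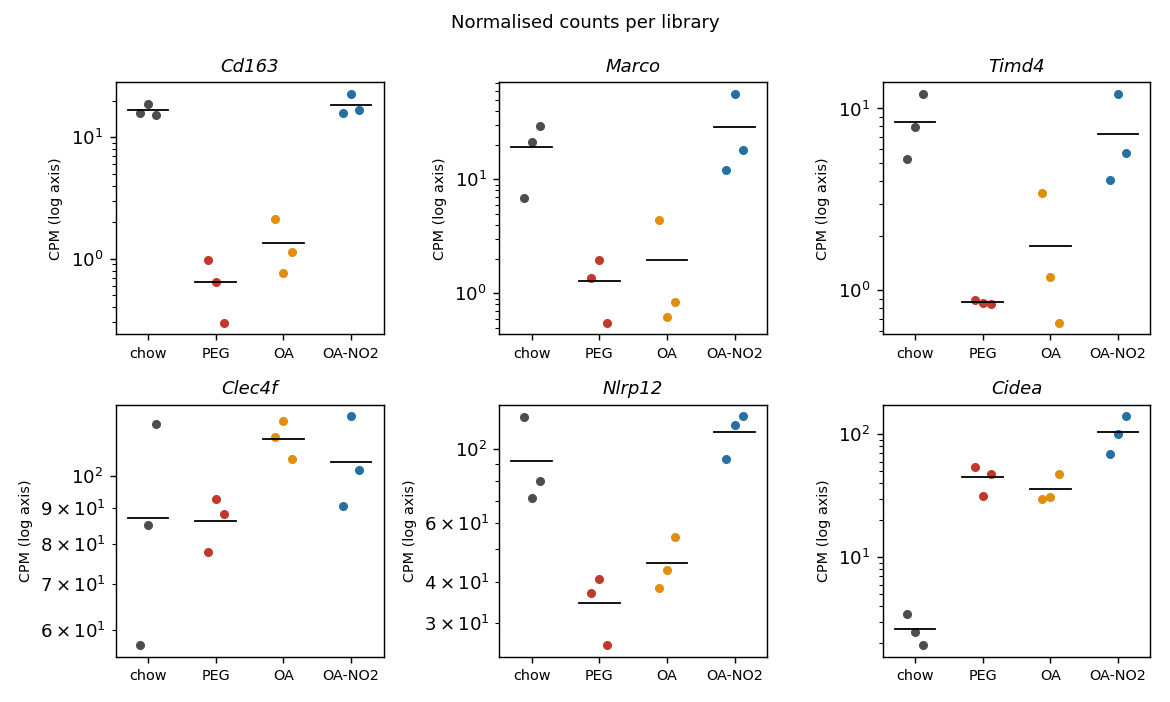
Each panel shows 1 gene, with CPM on a logarithmic vertical axis, the 4 groups on the horizontal axis (PEG is the vehicle), a point per library and a line at the group mean. Cd163 stood at 16.7 CPM in chow, 0.638 with vehicle, 1.35 with OA and 18.4 with OA-NO2, while Clec4f stood at 86.9, 86.2, 113 and 105.

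With OA-NO2, 19 lists passed camera against vehicle, 7 upward and 12 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.266) or with fry in 1 direction (lowest adjusted p = 0.0841), while the mixed form of fry passed 14. Outside the Kupffer list edgeR called no list gene over all genes. DESeq2 called 5 matrix, 3 monocyte-derived macrophage, 3 antigen presentation and 3 chemokine genes lower. It called 4 growth hormone, 4 lipid droplet, 2 fatty acid oxidation and 2 bile acid genes higher, 1 lipid droplet gene and 2 glucose genes lower, and at most 1 in each other list outside the Kupffer list, where it called 3 higher. Of 31 matrix genes 29 had negative values (median -1.2, adjusted p = 5.83e-16; adjusted p = 0.27 with an estimated correlation), and 19 fell adjusted over the list alone. Col1a1 stood at 17.1 ± 16.0 against 52.6 ± 26.0 CPM (log2 -1.61 ± 0.66, adjusted p = 0.26), Dpt, dermatopontin, at -2.06 ± 0.53, Thbs2 at -1.42 ± 0.37, Vim at -0.95 ± 0.23 and Timp1 at -2.29 ± 0.69 (adjusted p = 0.173). Of 14 monocyte-derived macrophage genes 14 had negative values (median -1.46, adjusted p = 2.47e-11; adjusted p = 0.266 with an estimated correlation), and 11 fell adjusted over the list alone. Trem2 stood at 4.83 ± 2.93 against 17.7 ± 6.09 CPM (-1.87 ± 0.50, adjusted p = 0.158), Lyz2, lysozyme, at -1.32 ± 0.35, Ccr2, the monocyte chemokine receptor, at -1.55 ± 0.43, and Gpnmb at -1.96 ± 0.78 (adjusted p = 0.251). Of 9 antigen presentation genes 9 had negative values (median -1.01, adjusted p = 1.08e-08; adjusted p = 0.266 with an estimated correlation), and 9 fell adjusted over the list alone, with H2-Aa at -1.29 ± 0.33, H2-Ab1 at -1.29 ± 0.33 and H2-Eb1 at -1.19 ± 0.30. Of 21 chemokine genes 19 had negative values (median -0.61, adjusted p = 5.64e-06; adjusted p = 0.266 with an estimated correlation), and 3 fell adjusted over the list alone, with Ccl5 at -1.30 ± 0.37 and Ccl22 at -2.08 ± 0.54.

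The 7 upward lists were mostly metabolic. Of 24 fatty acid oxidation genes 23 had positive values (median 0.44, adjusted p = 5.78e-10; adjusted p = 0.266 with an estimated correlation), and 7 rose adjusted over the list alone. Angptl4, a lipase inhibitor, stood at 1.40 ± 0.33, Acot1, an acyl-CoA thioesterase, at 1.89 ± 0.50, Cyp4a10 at 1.52 ± 0.43 and Cyp4a14 at 1.62 ± 0.48 (adjusted p = 0.172). Of 17 growth hormone and sex-biased genes 13 had positive values (median 0.96, adjusted p = 2.26e-06; adjusted p = 0.266 with an estimated correlation), and 11 rose and 1 fell adjusted over the list alone, with Elovl3, a fatty acid elongase, at 2.18 ± 0.52 and the close copies Cyp4a12a and Cyp4a12b at 1.75 ± 0.38 and 1.90 ± 0.46. Of 17 hepatocyte identity genes 16 had positive values (median 0.46, adjusted p = 0.000364; adjusted p = 0.335 with an estimated correlation), 0 adjusted over the list alone, with Hnf4a, the hepatocyte transcription factor, at 0.62 ± 0.18, Alb at 0.67 ± 0.28 and Arg1 at 0.56 ± 0.24. Drug metabolism stood at a median of 0.32 (17 of 22 positive, 1 rose adjusted over the list alone, adjusted p = 0.000444; adjusted p = 0.371 with an estimated correlation). Nr1i3, the receptor CAR, stood at 1.5 ± 0.39, Por at 0.78 ± 0.25 and Cyp2f2 at 1.32 ± 0.46. Bile acid genes stood at 0.29 (12 of 17 positive, 3 rose and 1 fell adjusted over the list alone, adjusted p = 0.0076; adjusted p = 0.309 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase, stood at 1.60 ± 0.38 and Slco1a1 at 2.04 ± 0.56. Heat shock genes stood at 0.32 (12 of 13 positive, 0 adjusted over the list alone, adjusted p = 0.00446; adjusted p = 0.266 with an estimated correlation). Hsph1 stood at 0.72 ± 0.24, and lipogenesis genes at 0.26 (15 of 21 positive, 1 rose adjusted over the list alone, adjusted p = 0.0334; adjusted p = 0.372 with an estimated correlation). Acacb stood at 0.92 ± 0.30 and Elovl6 at -0.56 ± 0.18.

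The other 8 downward lists had negative medians too. Cholangiocyte genes had a median of -1.77 (10 of 10 negative, 5 fell adjusted over the list alone, adjusted p = 9.63e-05; adjusted p = 0.335 with an estimated correlation). Krt19 stood at -2.35 ± 0.67. Proliferation genes stood at -0.64 (16 of 18 negative, 2 fell adjusted over the list alone, adjusted p = 1.56e-05; adjusted p = 0.266 with an estimated correlation). Mki67 stood at -1.10 ± 0.28 and Top2a at -1.07 ± 0.31. Lymphocyte genes stood at -0.86 (14 of 16 negative, 2 fell adjusted over the list alone, adjusted p = 0.00051; adjusted p = 0.299 with an estimated correlation). The B-cell genes Ms4a1 stood at -1.99 ± 0.52 and Cd79b at -1.33 ± 0.41. Stellate cell genes stood at -0.40 (10 of 12 negative, 0 adjusted over the list alone, adjusted p = 0.0076; adjusted p = 0.371 with an estimated correlation). Cygb stood at -0.94 ± 0.29. The remaining downward lists held 0 genes adjusted over the list alone. They were the interferon response (median -0.27, adjusted p = 0.0078; adjusted p = 0.344 with an estimated correlation; Gbp2 -0.80 ± 0.23, Ifit2 -0.79 ± 0.24) and antioxidant genes (-0.21, adjusted p = 0.013; adjusted p = 0.268 with an estimated correlation; Gstm3 -1.32 ± 0.40, Nqo1 -0.34 ± 0.23). The others were immediate early genes (-0.76, adjusted p = 0.0213; adjusted p = 0.53 with an estimated correlation; Junb -1.2 ± 0.64) and the unfolded protein response (-0.17, adjusted p = 0.0453; adjusted p = 0.477 with an estimated correlation; Manf -0.72 ± 0.23). Cholesterol synthesis did not pass (median 0.13, mean -0.004, camera upward; median -0.08 with library size alone; adjusted p = 0.467), nor did lipid droplet genes (0.21, -0.004 with library size alone; adjusted p = 0.122), where 4 rose and 2 fell adjusted over the list alone. Median and mean also differed in sign for glucose genes (0.02 and -0.07, camera downward) and acute phase genes (0.02 and -0.1, camera downward). For mitochondrial genes they were -0.01 and -1.58 with camera pointing upward, and none of these lists passed. Intervals were -0.59 to 0.33 for Cidec, -0.50 to 1.01 for Cd36, -0.12 to 0.80 for Scd1, -0.71 to 0.57 for Cyp7a1, -1.78 to 0.44 for Sqle, -1.64 to 0.33 for Fgf21, -0.56 to 0.62 for Hmox1 (estimate 0.03, -0.16 with library size alone) and -0.15 to 1.21 for Hspa1b.

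The nitro group is the structural difference between OA-NO2 and OA, which were infused at the same rate, and their livers were compared directly. Cd163 stood at 18.4 ± 3.81 CPM with OA-NO2 against 1.35 ± 0.709 with OA (SD, n = 3 each), a log2 rise of 3.76 ± 0.35 (SE; 95% interval 3.0 to 4.52, edgeR adjusted p = 0.00085, 2.52e-24 to 0.00714 over all alternatives). It was the only gene called by edgeR, with 1740 genes at an unadjusted p under 0.05 (762 higher, 978 lower) where chance gives 723. Cidea stood at 104 ± 35.4 against 35.9 ± 9.73 CPM (1.53 ± 0.28, edgeR adjusted p = 0.243, DESeq2 adjusted p = 0.000519, 0.000519 to 0.824 over all alternatives), and Nlrp12, chosen here after its values were seen, at 112 ± 16.7 against 45.4 ± 8.37 (1.31 ± 0.23, edgeR adjusted p = 0.243, DESeq2 adjusted p = 0.000519, 0.000519 to 0.812 over all alternatives). Marco and Timd4, likewise chosen after their values were seen, stood at 3.85 ± 0.77 and 2.03 ± 0.52 (edgeR adjusted p = 0.313 for each, DESeq2 adjusted p = 0.0172 and 0.0272, 0.0172 to 0.696 and 0.0272 to 0.696 over all alternatives). On the lower side the lowest p values were in Steap4 (-1.32 ± 0.23, adjusted p = 0.243), Ntrk2 (-1.10 ± 0.19, adjusted p = 0.243), the Langerhans-cell lectin Cd207 (-1.29 ± 0.26) and Tlr13 (-1.47 ± 0.29), the last 2 at an adjusted p of 0.313. DESeq2 called these 4 genes, at adjusted p of 0.000133, 0.000707, 0.00322 and 0.00376, each the lowest over all alternatives, where the highest were 0.725, 0.696, 0.859 and 0.859. DESeq2 called 51 genes (27 higher, 24 lower), edgeR without a filter on low counts 10, and edgeR without OA replicate 3 130 (44 higher, 86 lower), or 2 without OA-NO2 replicate 2. CPM values did not overlap in 14.3% of genes, where chance gives 10%.

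Between OA-NO2 and OA, DESeq2 called 3 Kupffer and 2 lipid droplet genes higher and at most 1 in each other list. In this comparison 19 lists passed camera, 8 upward and 11 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.222) or with fry in 1 direction (lowest adjusted p = 0.0617), while the mixed form of fry passed 8. Chemokine genes had a median of -0.73 (20 of 21 negative, 7 fell adjusted over the list alone, adjusted p = 4.67e-09; adjusted p = 0.222 with an estimated correlation). Tlr2 stood at -1.12 ± 0.30 and Ccl5 at -1.37 ± 0.37. Monocyte-derived macrophage genes stood at -1.28 (14 of 14 negative, 7 fell adjusted over the list alone, adjusted p = 4.67e-09; adjusted p = 0.259 with an estimated correlation). Lyz2 stood at -1.32 ± 0.35 and Trem2 at -1.64 ± 0.49. Matrix genes stood at -0.86 (29 of 31 negative, 0 adjusted over the list alone, adjusted p = 4.1e-08; adjusted p = 0.436 with an estimated correlation). Thbs2 stood at -1.19 ± 0.37. Antigen presentation genes stood at -0.96 (9 of 9 negative, 6 fell adjusted over the list alone, adjusted p = 8.98e-08; adjusted p = 0.259 with an estimated correlation). Ctss, cathepsin S, stood at -1.03 ± 0.31. Acute phase genes stood at -0.52 (15 of 17 negative, 4 fell adjusted over the list alone, adjusted p = 2.49e-05; adjusted p = 0.259 with an estimated correlation). Lcn2 stood at -2.10 ± 0.58, and neutrophil genes at -1.39 (5 of 5 negative, 0 adjusted over the list alone, adjusted p = 0.00106; adjusted p = 0.259 with an estimated correlation). S100a8 stood at -1.77 ± 0.67 and S100a9 at -1.88 ± 0.72. The other downward lists were proliferation (-0.60, 2 fell adjusted over the list alone), interferon response (-0.36, 2 fell adjusted over the list alone), lymphocytes (-0.74, 0 adjusted over the list alone), unfolded protein response (-0.28, 0 adjusted over the list alone) and cholangiocytes (-1.28, 0 adjusted over the list alone), at adjusted p = 0.259 to 0.564 with an estimated correlation.

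Upward between OA-NO2 and OA were fatty acid oxidation genes (median 0.26, 23 of 24 positive, 0 adjusted over the list alone, adjusted p = 4.3e-06; adjusted p = 0.274 with an estimated correlation). Acot1 stood at 1.36 ± 0.49 and Angptl4 at 1.0 ± 0.33. Growth hormone and sex-biased genes stood at 0.66 (14 of 17 positive, 0 adjusted over the list alone, adjusted p = 6.87e-05; adjusted p = 0.259 with an estimated correlation). Lipid droplet genes moved both ways (median 0.13, 13 of 20 positive, 6 rose and 2 fell adjusted over the list alone, adjusted p = 0.0048; adjusted p = 0.222 with an estimated correlation). The fatty acid transporter Slc27a1 stood at 1.17 ± 0.29 and Vldlr at -1.0 ± 0.27. The 4 tested adipose carryover genes, Cidea among them, had a median of 1.09 for OA-NO2 over OA and 0.95 for OA-NO2 over vehicle. Of these 2 and 3 rose adjusted over the list alone, and over all genes edgeR called none and DESeq2 1 in each. Cfd stood at 1.17 ± 0.62 over OA and 2.13 ± 0.64 over vehicle. Heat shock genes stood at 0.37 (1 rose adjusted over the list alone; Bag3 0.67 ± 0.17), hepatocyte genes at 0.38 (0 adjusted over the list alone), oxidative phosphorylation at 0.23 (0 adjusted over the list alone), cholesterol synthesis at 0.17 (1 rose adjusted over the list alone; Tm7sf2 0.91 ± 0.20) and lipogenesis at 0.15 (1 rose adjusted over the list alone; Fads1 0.58 ± 0.16), at adjusted p = 0.259 to 0.635 with an estimated correlation. Median and mean differed in sign for Kupffer genes (-0.6 and 0.33, camera upward), glucose genes (0.03 and -0.05, camera downward), red blood cells (0.05 and -0.06, camera downward) and nitric oxide genes (-0.06 and 0.01, camera upward), of which none passed. Where the fatty acids were not shown to differ, the 95% interval of the log2 difference was -0.40 to 0.51 for Scd1 (estimate 0.06, -0.05 with library size alone), -0.55 to 0.37 for Cidec, -0.88 to 0.62 for Cd36, -0.73 to 0.56 for Cyp7a1, -1.21 to 1.05 for Sqle and -0.79 to 1.2 for Fgf21. It was -0.89 to 0.30 for Hmox1, -0.70 to 0.30 for Nqo1, -0.11 to 1.26 for Hspa1b, -2.42 to 0.39 for Col1a1 and -2.89 to 0.08 for Timp1. For Cyp4a14, Trem2 and Gpnmb the intervals were 0.20 to 2.26, -2.70 to -0.57 and -3.83 to -0.46, with adjusted p of 0.363, 0.313 and 0.348.

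Each treated group was also compared with chow. OA over chow gave 1238 called genes (916 higher, 322 lower) and OA-NO2 over chow 99 (63 higher, 36 lower), by edgeR. The counts depended on the scaling and on single libraries. Library size alone called 3776 (3649 higher, 127 lower) and 1127 (1099 higher, 28 lower). OA over chow called 2232 without OA replicate 3, 347 without OA replicate 1, 379 without OA replicate 2, 465 without chow replicate 1 and 567 without chow replicate 2. OA-NO2 over chow called 15 without chow replicate 3 or OA-NO2 replicate 1, 17 without OA-NO2 replicate 3, 19 without chow replicate 2 and 39 without chow replicate 1. Cd163 was lower with OA (-3.62 ± 0.35, adjusted p = 0.000282) and stood at 0.14 ± 0.30 with OA-NO2 (adjusted p = 0.827). Cidea was higher in both, by 3.85 ± 0.34 and 5.38 ± 0.35. Gstm3 was higher in both, by 3.76 ± 0.48 and 3.02 ± 0.47, and Cidec by 1.73 ± 0.22 and 1.64 ± 0.22. Col1a1 stood at 4.45 ± 0.84 with OA (adjusted p = 0.00844) and 3.44 ± 0.84 with OA-NO2 (adjusted p = 0.0695), a pair whose difference is the interval of -2.42 to 0.39 given above. Cfd, an adipose-rich complement factor, rose by 3.44 ± 0.74 with OA and 4.61 ± 0.76 with OA-NO2.

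To measure how far the treatments opposed the diet response, the 2786 diet-called genes were followed in the other comparisons. Between OA-NO2 and OA, which share no library with the diet comparison, 2190 of them (78.6%, jackknife SE 12.0) had the sign opposite to the diet, against 50.3% in simulations with no effect, 85.6% of the diet-raised and 69.1% of the diet-lowered genes. OA-NO2 over vehicle opposed 2648 of them (95.05%, SE 3.21), where sharing the vehicle libraries alone gave 62.3%. With OA over chow as the diet response, which shares no library, the share was 93.6% of 1238 genes, against 50% in simulations. OA over vehicle opposed 2299 (82.5%, SE 24.0, simulated 62.3%), and 55.6% without OA replicate 3. With OA-NO2 over chow as the diet response it was 68.7% of 99 genes, against 50% in simulations. Regression of each comparison on the diet response gave slopes of -0.29 for OA-NO2 over OA, -0.45 for OA-NO2 over vehicle and -0.17 for OA over vehicle. In simulations with no effect the mean slopes were -0.001, -0.06 and -0.06, the last 2 comparisons sharing the vehicle libraries with the diet response. All these simulations drew genes independently, and so leave out differences between livers that move many genes together. Of the 10 splits of the OA and OA-NO2 libraries, 4, the real one included, gave an opposed share at least as far from 50% as 78.6%. Cd163 and Nlrp12 were the rule's diet-opposed called genes. Across genes, which are not independent replicates, the OA and OA-NO2 responses over vehicle had a Pearson r of 0.539, against 0.496 simulated for the shared vehicle libraries, and 0.168 without OA replicate 3. The covariance was 0.115, against 0.0598 simulated, a difference of 0.0548.

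**Figure D4:**
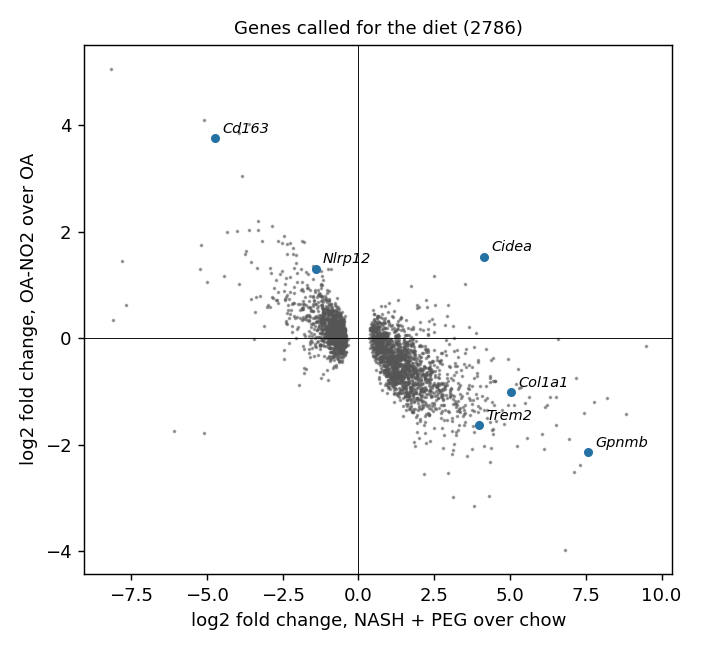
Each point is 1 of the 2786 genes called between vehicle and chow, with its log2 fold change for the diet (vehicle over chow) on the horizontal axis and for OA-NO2 over OA on the vertical axis; labelled genes are larger points. Of these genes 78.6% had opposite signs on the axes, and Cd163 stood at -4.71 and 3.76.

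On the line from the chow mean (0%) to the vehicle mean (100%), OA libraries stood at 104%, 96.3% and 48.6% (replicates 1 to 3) and OA-NO2 libraries at 67.2%, 38.1% and 49.7%. The means were 82.9% ± 30.0 for OA and 51.7% ± 14.6 for OA-NO2 (SD, n = 3 each), a difference of -31.3 percentage points with a two-sided exact permutation p of 0.3, the smallest possible being 0.1. In simulations in which a group was like vehicle, its mean stood at 93.6% for OA and 93.4% for OA-NO2. These drew genes independently, and so lack the spread between libraries seen here. Tested against its group's position on this line, 4 of 14469 genes departed with OA-NO2, all higher (1235 at an unadjusted p under 0.05), and 0 with OA (426 at an unadjusted p under 0.05) by edgeR, the test not being run with another tool. The test took the group's mean position as exact, so its errors and adjusted p leave out the spread between libraries. These 4 genes were named after their values were seen. Cidea (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785) lay 3.23 ± 0.24 above its position on the log2 scale (adjusted p = 5.31e-05), Cd163 2.58 ± 0.27 (adjusted p = 0.00171) and Adam11 1.97 ± 0.22 (adjusted p = 0.00193). The fourth, B430212C06Rik (chromosome 18, 67321209 to 67344103), overlaps the start of Cidea on the opposite strand, so that its value of 2.54 ± 0.33 (adjusted p = 0.0106) and that of Cidea may share reads and are uncertain.

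**Figure D5:**
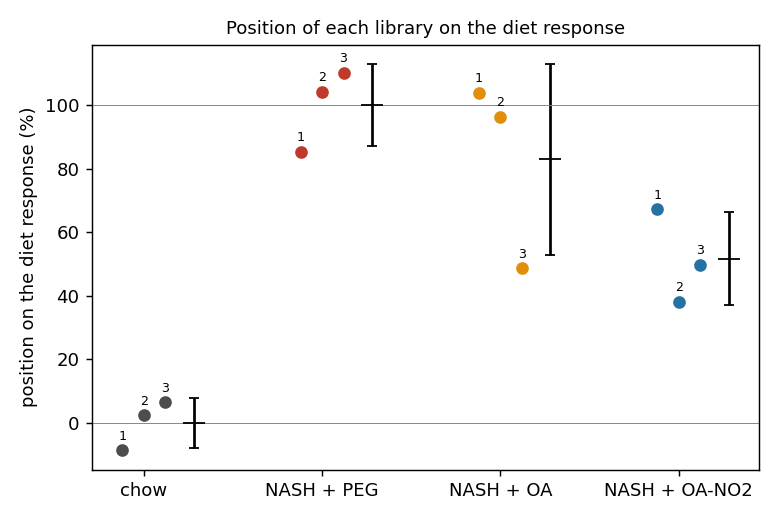
The vertical axis gives each library's position on the diet response in percent, from the chow mean (0) to the vehicle mean (100), and the horizontal axis the 4 groups; points are libraries with their replicate number, and the bar is the mean with its SD. OA replicate 3 stood at 48.6%, and the OA-NO2 libraries between 38.1% and 67.2%.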

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

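The tests of Kupffer cell number, of position on the diet response, of exchanged libraries, of single libraries for Marco and Timd4 and of a nuclear copy were chosen only after the result was seen, while those of scaling, single libraries for Cd163, depth and short transcripts were chosen before.

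Cd163 drew attention because its responses to OA and to OA-NO2 over vehicle differed when the difference was tested directly, by 3.76 on the log2 scale (95% interval 3.0 to 4.52, edgeR adjusted p = 0.00085, 0.00057 to 0.00714 on leaving out 1 library).

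Cd163, Marco and Timd4 were each higher with OA-NO2 than with vehicle by at least 3.07 on the log2 scale, although only Cd163 was called by edgeR. The other 10 Kupffer genes did not rise with them (median -0.37, SD 0.305, range -0.66 to 0.28). This cannot decide whether resident Kupffer cells were more numerous, since the list also holds genes common to macrophages. Genes of monocyte-derived macrophages, whose fall could mask such a rise, had a median of -1.46 in this comparison. Scaling is argued against, since the smallest of the 3 stayed at 2.85 or more under other scalings, and so is 1 aberrant OA-NO2 library as the whole cause. Without any 1 OA-NO2 library Cd163 stayed at 4.67 or more, and the smaller of Marco and Timd4 at 2.49 ± 0.527 (SE) or more. Without OA-NO2 replicate 2 the edgeR adjusted p of Marco and Timd4, 0.0965 with all libraries, was 0.344. A mere return along the diet response is argued against for Cd163, which lay 2.58 ± 0.271 (SE) above the group's position (adjusted p = 0.00171). That error takes the position as exact and leaves out the spread of the OA-NO2 libraries (38.1% to 67.2%). Even so, Cd163 rose over vehicle by 4.49 to 5.32 on leaving out 1 library, against a diet change of -4.71. For Marco and Timd4 it cannot be told apart from other causes, since their distances of 2.59 ± 0.58 and 1.47 ± 0.421 had adjusted p of 0.294 and 0.456. An effect of nitro-oleic acid on resident macrophages stays open and untested.

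OA replicate 3 stood at 48.6% of the diet response, against 104% and 96.3% for the other OA libraries. An exchange with an OA-NO2 library cannot be told apart from other causes. With OA replicate 3 exchanged for OA-NO2 replicate 1, 164 genes were called between the groups against 1 with the labels as given, but OA-NO2 replicate 1 stood at 67.2%, below both other OA libraries. This was the highest count of the 3 such exchanges. Cd163 stayed called between OA-NO2 and OA without any 1 of these 6 libraries (adjusted p 0.00057 to 0.00714). Depth is argued against, since thinning all libraries to the lowest total moved its position by 1.65 percentage points. A difference between animals stays open and untested, as does a single wrong label.

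Of 13 mitochondrial protein-coding transcripts, 6 neighbouring ones (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, chromosome M, 7013 to 10173) varied within groups with an SD of 3.43 to 3.89 log2 units, against 0.178 to 0.351 for the other 7. Loss of short transcripts is argued against, since 42 nuclear transcripts as short differed by a median of -0.0211 (SD 0.224) between the libraries concerned, against at least 6.28 for the uneven ones. Reads shared with a copy on chromosome 1 (24611535 to 24616197) cannot be told apart from other causes: of 12 transcripts, those with most windows in the copy were the more uneven in 97.2% of 36 pairs, but mt-Nd4, with 61.5% of its windows in the copy, had an SD of 0.335. These pairs leave out the uneven mt-Atp8 (SD 3.72), whose place in the copy has no annotated pseudogene, so that it was not searched. The copy itself held at most 2134 CPM (vehicle replicate 1, where the 6 transcripts summed to 101 CPM). In the 3 libraries rich in them the 6 summed to 40183 to 52349 CPM, so counts on the copy did not make up the difference. No biological explanation was tested. A term for the 3 rich libraries called 0 genes by edgeR (406 at an unadjusted p under 0.05, not run with another tool). It missed even the 6, so it cannot show whether these libraries differ otherwise.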

How the results depend on the processing

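The thinning of libraries, the term for 3 libraries rich in uneven mitochondrial transcripts, the removal of mitochondrial genes, and the settings of the diet position were chosen only after the data were seen. No named gene called by edgeR turned direction under DESeq2, median-ratio factors or any left-out library, while list medians and genes such as Dnajc3 did with library size alone. Without OA replicate 3 the opposed share of OA over vehicle fell from 82.5% to 55.6%, under its simulated 62.3%. Calls between OA-NO2 and vehicle were 3 higher and 0 lower by edgeR, but 131 higher and 169 lower by DESeq2. Cd163 was called in both OA-NO2 comparisons under DESeq2, median-ratio factors and every left-out library. No paired analysis was possible because the replicate numbers only follow the order of deposit.

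Counts of called genes moved with the setting, and where not stated the cause was not tested. DESeq2 called 300 genes between OA-NO2 and vehicle, 51 between OA-NO2 and OA, 1882 between OA and chow (1252 higher, 630 lower) and 653 between OA-NO2 and chow (384 higher, 269 lower). limma-voom called 769 between OA and chow and 21 between OA-NO2 and chow. Library size alone called 5758 between vehicle and chow, 3776 between OA and chow and 1127 between OA-NO2 and chow, nearly all higher, which the shift of all genes against chow accounts for by construction. No filter on low counts gave 151 between OA-NO2 and vehicle, 10 between OA-NO2 and OA and 262 between OA-NO2 and chow, and a mean of at least 1 CPM gave 1 between OA-NO2 and vehicle. Only the 2 groups compared gave 62 between OA-NO2 and vehicle, 776 between OA and chow and 53 between OA-NO2 and chow. An adjusted p under 0.10 gave 12, 2254 and 461 in the same comparisons. Thinning to the lowest total gave 5 between OA-NO2 and vehicle and 55 between OA-NO2 and chow. The mitochondrial term gave 1 between OA-NO2 and vehicle, 585 between OA and chow and 14 between OA-NO2 and chow.

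Leaving out 1 library gave 1200 to 2276 called genes between vehicle and chow, 1 to 4 between OA-NO2 and vehicle, 1 to 130 between OA-NO2 and OA, 347 to 2232 between OA and chow and 15 to 71 between OA-NO2 and chow, the lowest and highest counts of OA over chow being without OA replicates 1 and 3 and the 130 without OA replicate 3. OA against vehicle stayed at 0 by edgeR under every setting (564 genes at an unadjusted p under 0.05). With an estimated correlation 2 lists passed between vehicle and chow and 0 in each other comparison among the NASH-diet groups; fry passed 20 and, in the others, 0, and its mixed form 28 and, in the others, 0 (OA over vehicle), 14 and 8. Leaving out 1 library gave 4 to 12 lists for OA over vehicle. The opposed share between OA-NO2 and OA was 91.7% over genes with a diet fold beyond 1, and 69.9% to 87.3% on leaving out 1 library. For OA-NO2 over vehicle it was 90.3% (without OA-NO2 replicate 3) to 97.3%, and for OA over vehicle 55.6% (without OA replicate 3) to 90.8%. The correlation of the responses was 0.168 (without OA replicate 3) to 0.659 on leaving out 1 library, and 0.712 over the genes called between vehicle and chow.

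Of 93 named genes called between vehicle and chow, 71 kept their call under DESeq2, median-ratio factors and every left-out library, 21 lost it on leaving out a library, and Slco1a1 had no adjusted p in DESeq2, where its log2 fold change was -3.92. Of 83 named genes not called between OA-NO2 and vehicle, DESeq2 called 29, and of 84 between OA-NO2 and OA, 13. Thinning to the lowest total, 8462590 counts, gave 2374 called genes between vehicle and chow. Recovery of simulated 2-fold changes was 48% there and 40% to 50% in the comparisons without chow.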

Other observations

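The comparisons of single genes with chow, and the splits of the mitochondrial libraries, were chosen only after the values were seen, while the splits of the samples were planned.

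Against chow, lipid and antioxidant lists stood high with either fatty acid, as they did with vehicle (medians 0.45 and 0.72). Cholesterol synthesis genes were low with vehicle too (median -0.98), so these comparisons with chow hold the diet response. Lipid droplet and uptake genes rose with OA-NO2 as a group (median 0.54, camera adjusted p = 9.31e-13; adjusted p = 0.00117 with an estimated correlation), with 3 of 20 called and 12 rising and 1 falling adjusted over the list alone. With OA the list also passed (median 0.38, adjusted p = 6.04e-05; adjusted p = 0.0299 with an estimated correlation), with 8 up and 2 down, 9 and 2 adjusted over the list alone. Antioxidant genes passed with OA-NO2 (median 0.55, adjusted p = 5.03e-09; adjusted p = 0.0214 with an estimated correlation; 3 of 22 rose, 9 adjusted over the list alone) and with OA (median 0.62, adjusted p = 1.25e-08; adjusted p = 0.0299 with an estimated correlation; 8 rose, 13 adjusted over the list alone). Cholesterol synthesis genes were lower with OA-NO2 (median -0.72, adjusted p = 2.04e-13; adjusted p = 0.224 with an estimated correlation; 3 of 25 fell, 15 adjusted over the list alone) and with OA (median -0.89, adjusted p = 8.19e-15; adjusted p = 0.143 with an estimated correlation; 14 fell, 17 adjusted over the list alone). Among genes chosen after their values were seen, with OA-NO2 over chow Plin4, a lipid droplet coat protein, stood at 3.03, Slc13a3, a dicarboxylate transporter, at 1.78 and Adam11 at 3.15 on the log2 scale. Stard4 stood at -2.22, beside -1.60 with vehicle over chow, and Adh4, an alcohol dehydrogenase, at -1.14.

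Adipose carryover genes were few, but stood high with OA-NO2 over chow (median 2.51 of 4 tested, 2 called, 2 adjusted over the list alone), beside a median of 1.10 with vehicle over chow. Cidea and Cfd were those called, while Car3, the abundant carbonic anhydrase of fat cells that liver also expresses, stood at -0.38 ± 0.41 and Adrb3 at 0.41 ± 0.29.

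The 6 libraries of each comparison split into 3 against 3 in 10 ways, too few for a share under 0.05. Vehicle against chow called 2786 genes and no more than 0 in any other split (1 split as large), OA against chow 1238 and 0 (1), and OA-NO2 against chow 99 and 1 (1). OA-NO2 against vehicle called 3 and 1 (1), and OA against vehicle 0 in all 10 splits by edgeR (564 genes at an unadjusted p under 0.05 in the real split). OA-NO2 against OA called 1 gene, and 164 in the split of OA replicates 1 and 2 with OA-NO2 replicate 1 against the other 3 libraries, so that 2 splits were as large. The groups were thus not the split that called the most genes. That split set the 3 libraries highest on the diet response (104%, 96.3% and 67.2%) against the 3 lowest (48.6%, 38.1% and 49.7%), and its cause was not tested. For lists, the real value and the highest other were 20 and 23 between vehicle and chow (3 splits as large), 8 and 21 between OA and vehicle (7), 19 and 15 between OA-NO2 and vehicle (1) and 19 and 18 between OA-NO2 and OA (1). For the opposed share between OA-NO2 and OA they were 78.6% and 91.0% (4).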
